A study of Homo sapiens with 14 samples.

How the data were processed

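RNA was measured in 14 libraries of the myeloma lines MM1.S and H929. Per the labels, cells were grown in RPMI medium with 10% FBS and transduced with lentiviral scramble or anti-ZBP1 hairpins, RNA was extracted with Nucleospin kits, poly(A) RNA was selected, and libraries were made with NEBNext Ultra II kits. Per the submitters' processing notes, reads were handled with STAR 2.5.3a and DESeq2 1.24.0 on GRCh38 (hg38); neither the counting tool nor the annotation release is stated. No label states whether the libraries keep the strand, so reads of a gene may include reads from an overlapping gene: 110 of the 194 named genes overlap another annotated gene, 85 of them on the opposite strand.

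The deposited MM1.S table holds raw read counts per Ensembl gene, per the file headers, and its values are whole. The deposited H929 table is also named as raw counts, but its values are a normalized signal, counts that the authors divided by 1 size factor per library before they deposited them: multiplied back, every value is a whole number within 0.01. The authors also deposited, per the file headers, a table for each of the 4 hairpin comparisons with a log2 fold change, an adjusted p-value and a mean of normalized signal per gene, with the column names of DESeq2 results. Each table lists 58069 genes, of which 18 repeated identifiers were left out, leaving 58051; 22475 genes in MM1.S and 22315 in H929 carry no symbol. The columns of shRNA2 and of replicate 2 of the H929 scramble for shRNA1 were assigned by elimination.

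MM1.S counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and filterByExpr (minimum count 10), all 6 libraries in 1 fit over 17820 genes. The plan, made before the data were examined, was to use the same test for H929. Because its table does not hold counts, H929 was tested instead with limma 3.58.1 (trend) on log2 of the deposited value plus 1, all 8 libraries in 1 fit over the 18213 genes with a value of at least 10 in at least 2 libraries. The difference between the lines was tested with limma over 20370 genes and all 14 libraries, with MM1.S counts divided by size factors, so fold changes of H929 and of the line difference are on that log2 scale. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. The comparisons were each hairpin against its scramble group, the hairpins against each other, the H929 scramble groups against each other, and each hairpin's effect between the lines, all with 2 libraries per group. MM1.S libraries with the same replicate number deviated together from their group means (correlations across 11027 genes of 0.578 to 0.782 between the 3 groups), so the numbers were taken to pair them, and values with the number as a block are given for list and gene calls that changed and for list counts that moved by over 1.5-fold. The main MM1.S fit and the simulated MM1.S libraries leave this pairing out. No label says what the numbers stand for, and with 2 libraries a group each correlation rests on 1 difference per group. The H929 correlations were -0.176 to 0.207, which does not pair those libraries.

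The 27 gene lists were fixed before the data were examined; 787 entries matched the tables, for 753 genes. Lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, and also with an estimated correlation and with fry. A list was said to move in a line only if it passed in the same direction with both hairpins. Named genes followed a rule, also fixed beforehand: prespecified genes, the 10 highest and 10 lowest shared by the hairpins in each line and by all 4 comparisons, up to 4 per list and line, 5 each way for the line difference and 3 each way for the hairpin difference, with a mean of at least 5 CPM and a symbol where ranked. A few genes that the rule named, and some list members, are not reported here; they stayed in every test. Gene positions, 3' UTRs and transcripts came from GENCODE release 29.

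The gene tests were run on counts simulated from the real libraries, with 66 or 67 genes changed per fold size. Of genes with a simulated 2-fold change, 44.8% and 43.3% were called in MM1.S (shRNA1 and shRNA2), 76.1% and 77.6% in H929 and 26.9% and 29.9% in the line difference. For 4-fold changes these were 88.1% and 92.5%, 91.0% and 91.0%, and 76.1% and 80.6%. False calls were 18 and 18 among 17038 unchanged genes in MM1.S, 13 and 15 among 17466 in H929, and 9 and 5 among 19505 in the line difference. These rates need not hold for the data, where 36.6% to 53.4% of genes were called per hairpin comparison. Of the simulated H929 lists, 2 of 2 changed ones were found and 0 others called. The spread between libraries of a group was 2.36 to 30.3 times that of counting (chi-square per degree of freedom), so depth alone does not set the precision.

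Alternatives tried were median-of-ratios scaling (TMM for H929), the Wald test of DESeq2 1.42.0, no filter, only the compared groups in the fit, the replicate number as a block, each library left out in turn, and all 4 H929 scramble libraries as control. Chosen after the data were examined were edgeR on the reads recovered from the H929 table, a pseudocount of 5, limma for MM1.S, the other hairpin's scramble group as control, list tests of the differences, list tests against the other H929 scramble group, list members with the replicate block, the interferon and ATF4 lists without each MM1.S library, each MM1.S hairpin against 1 scramble library, named genes and shared calls against the other H929 scramble group, and a word search without and among genes that carry an Alu stretch. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.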

Results

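ZBP1, a cytosolic sensor of Z-form nucleic acids whose gene is induced by interferons, was depleted in 2 human multiple myeloma cell lines, MM1.S and H929, and poly(A)-selected RNA was sequenced to ask how their transcriptomes depend on it. Cells carried a lentiviral scrambled control or 1 of 2 hairpins against ZBP1, shRNA1 and shRNA2. The 14 libraries formed 7 groups of 2. In MM1.S, 1 scramble group served both hairpins, whereas H929 had a scramble group for each hairpin. The 6 MM1.S libraries held 20.46 to 28.42 M reads in genes and the 8 H929 libraries 15.93 to 22.25 M. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Reads of mitochondrial genes made up 9.87% to 10.2% of the MM1.S scramble libraries and 11.6% to 12.1% of the MM1.S knockdown libraries. In H929 they made up 6.63% to 7.22% of the 4 scramble libraries, 5.98% to 6.34% with shRNA1 and 8.72% to 8.80% with shRNA2. Log2 fold changes are knockdown over scramble and are given with their standard error, from groups of n = 2.

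ZBP1 itself (ENSG00000124256, GRCh38 chromosome 20, 57603846 to 57620576, minus strand) was lower in every knockdown library than in every scramble library of its line. In MM1.S it stood at 135 ± 7.75 CPM (SD, n = 2) with scramble, 24.9 ± 2.64 with shRNA1 and 16.7 ± 1.83 with shRNA2, which left 18.5% and 12.4% of the control level. In H929 it stood at 264 ± 5.77 with the scramble for shRNA1 and 119 ± 13.6 with shRNA1, which left 45.1%. The scramble for shRNA2 gave 199 ± 6.11 and shRNA2 72.2 ± 4.20, which left 36.3%. The log2 fold changes were -2.55 ± 0.15 (edgeR adjusted p = 3.5e-05) and -3.11 ± 0.16 (edgeR adjusted p = 2.4e-05) in MM1.S. In H929 they were -1.31 ± 0.09 (limma adjusted p = 8.6e-09) and -1.62 ± 0.09 (limma adjusted p = 4.2e-09). The knockdown was deeper in MM1.S than in H929 by -1.25 ± 0.17 with shRNA1 (limma adjusted p = 2.6e-04) and by -1.48 ± 0.17 with shRNA2 (limma adjusted p = 3.1e-04).

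**Figure D1:**
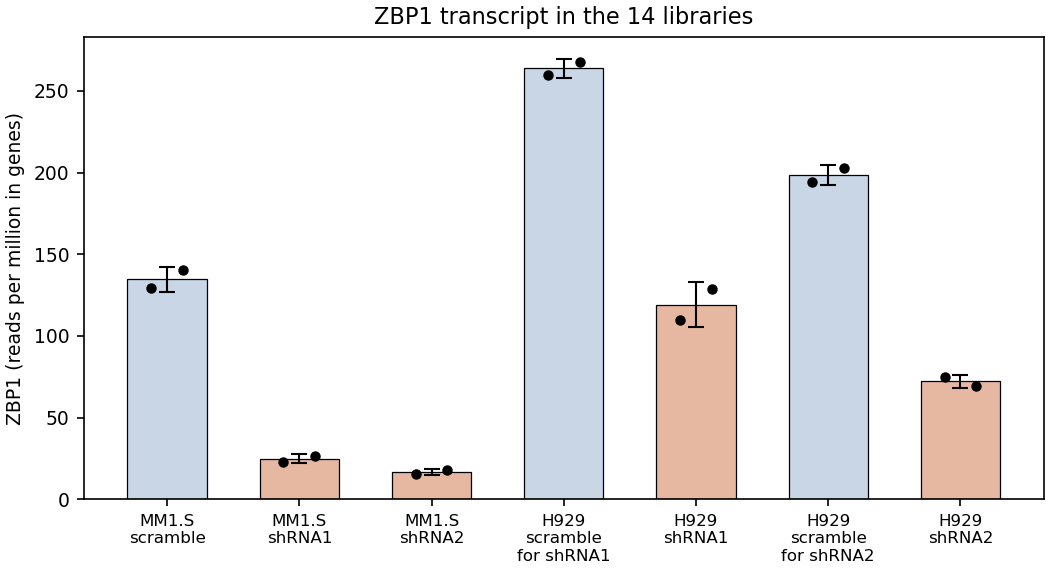
ZBP1 in CPM, reads scaled to the library's reads in genes, for each of the 7 groups. Bars are group means, error bars are the SD (n = 2) and points are single libraries; the MM1.S means are 135, 24.9 and 16.7, and the H929 means are 264, 119, 199 and 72.2.

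In MM1.S, genes of DNA replication and of mitosis were lower with both hairpins. All 50 measured DNA replication and G1/S genes and all 62 G2/M and mitosis genes fell with each. Camera's adjusted p was 0.0980 to 0.191 with an estimated correlation. Lists of plasma cell identity, protein folding in the ER, cholesterol synthesis, glycolysis, ribosome biogenesis, G1 cyclins (13 and 12 of 27 genes) and the heat shock response also fell with both hairpins, with an adjusted p of 0.0980 to 0.552 with an estimated correlation. The type I interferon-stimulated genes were the only list of the 26 tested in MM1.S that rose with both (16 and 17 of 35 genes; adjusted p = 0.191 and 0.0980 with an estimated correlation). ABCG1 and ABCA1, which export cholesterol from cells, rose by 5.18 ± 0.24 and 4.49 ± 0.26 with shRNA1 and by 3.19 ± 0.24 and 1.28 ± 0.26 with shRNA2. Among 17820 genes tested with edgeR, 3173 were higher and 3516 lower with shRNA1, of which 1671 and 1538 by 2-fold or more. With shRNA2, 2661 were higher and 3865 lower, of which 1001 and 2152 by 2-fold or more. The hairpins shared 1112 higher and 1897 lower genes, and 491 moved in opposite directions; independent lists would share 474 and 763, with 1213 opposite. Unchanged groups simulated against the same 2 scramble libraries shared at most 2 calls, and their fold changes had a Pearson correlation across genes of 0.482 ± 0.0108 (SD, 20 simulations) against 0.512 observed. Their covariance was 0.0551 ± 0.00196 against 0.484. Genes are not independent replicates and the hairpins share their controls. Set against 1 scramble library each (replicate 1 for shRNA1 and 2 for shRNA2), the hairpins shared 703 higher and 1471 lower genes, with 336 opposite, where independent lists would give 298, 577 and 843. With the 2 libraries exchanged they shared 723 and 1469, with 436 opposite, against 331, 611 and 910. The correlations were then 0.379 and 0.324 and the covariances 0.393 and 0.350, so most of the excess stayed without a shared library, though anything both scramble libraries have in common remains in each. Without 1 library each hairpin's counts fell, most without its replicate 1, and shared counts fell most without shRNA2 replicate 1 (ranges below). With the replicate number as a block, 5068 were higher and 5513 lower with shRNA1 and 4779 higher with shRNA2, with 2412 and 3336 shared and 1680 opposite.

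Within the MM1.S cell cycle lists, the median log2 fold change of the 50 DNA replication and G1/S genes was -2.43 with shRNA1 (camera adjusted p = 1.6e-82) and -2.01 with shRNA2 (camera adjusted p = 6.9e-60). With an estimated correlation the adjusted p was 0.191 and 0.127. For the 62 G2/M and mitosis genes the medians were -2.68 (camera adjusted p = 1.7e-118) and -2.84 (camera adjusted p = 1.8e-132), and the adjusted p with an estimated correlation was 0.191 and 0.0980. The counts were again 50 and 62 when adjusted over the list alone. RRM2, the small subunit of ribonucleotide reductase, changed by -3.44 ± 0.17 and -2.81 ± 0.17 with shRNA1 and shRNA2. MCM10, which helps start replication at origins, changed by -3.23 ± 0.20 and -3.40 ± 0.20. BIRC5 (survivin) changed by -2.76 ± 0.17 and -4.67 ± 0.19, and KIF20A, a kinesin of late mitosis, by -3.66 ± 0.17 and -3.55 ± 0.17. Of 27 genes of G1 cyclins, CDKs and the RB family, 13 fell with shRNA1, MYBL2 and CDK2 among them, and 5 rose (CDKN1C, E2F5, CDKN1B, E2F6 and CDKN2B). With shRNA2, 12 fell and 3 rose (CDKN2B, CDKN2A and RBL2); adjusted over the list alone, 14 fell and 6 rose with shRNA1, and 12 and 3 with shRNA2. The list medians were -0.30 and -0.24 (camera adjusted p = 0.00547 and 0.00445), and with an estimated correlation the adjusted p was 0.191 and 0.177. In limma on log2 values, 9 lists moved with both hairpins in MM1.S, and the G1 cyclin list was not among them. A block on the replicate number brought its genes higher with shRNA2 to 6, and left 50 and 62 genes lower in the other 2 lists.

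Of 35 measured type I interferon-stimulated genes in MM1.S, 16 rose and HERC5 fell with shRNA1, 17 rose while HERC5 and SAMD9 fell with shRNA2, and 14 rose with both. Adjusted over the list alone, 19 rose and 2 fell with shRNA1, and 20 and 2 with shRNA2. The medians were 0.56 (camera adjusted p = 4.6e-05) and 0.61 (camera adjusted p = 1.5e-07), and the adjusted p with an estimated correlation was 0.191 and 0.0980. MX1, an antiviral GTPase, rose by 1.81 ± 0.12 and 1.55 ± 0.11, and XAF1, a pro-apoptotic protein, by 2.72 ± 0.28 and 2.95 ± 0.28. DDX60, a helicase linked to RNA sensing, rose by 2.54 ± 0.29 and 4.98 ± 0.29. IRF3, a transcription factor activated downstream of nucleic acid sensors, gave 0.23 ± 0.16 and 0.39 ± 0.16 (edgeR adjusted p = 0.275 and 0.0834), and TBK1, its kinase, -0.35 ± 0.19 and 0.14 ± 0.19 (edgeR adjusted p = 0.189 and 0.587). The 24 genes of nucleic acid sensing and IRF3 activation did not pass as a list (camera adjusted p = 0.314 and 0.902; medians 0.29 and 0.23): 9 rose and 3 fell with shRNA1 (ZBP1 itself, MB21D1 and MAVS), and 6 rose and 4 fell with shRNA2 (ZBP1, TLR7, MB21D1 and TMEM173). Adjusted over the list alone, 9 and 4, then 6 and 4, did. TBKBP1, an adaptor of TBK1, rose by 2.12 ± 0.32 and 1.61 ± 0.33, while MB21D1, which encodes the DNA sensor cGAS, changed by -1.09 ± 0.15 and -0.92 ± 0.15. TMEM173 (STING) had 24 and 25 reads in the scramble libraries, 9 and 23 with shRNA1, and 2 and 4 with shRNA2. With the replicate number as a block, IRF3 passed with both hairpins (edgeR adjusted p = 0.00301 and 7.7e-05) and TBK1 with shRNA1 (edgeR adjusted p = 7.2e-04), and 12 sensing genes rose and 7 fell with shRNA2, while MAVS, ZBP1, MB21D1, DDX41 and TBK1 fell with shRNA1. In the same fit 24 interferon-stimulated genes rose and 5 fell with shRNA1 (BST2, HERC5, ISG20, SAMD9L and SAMD9), and 23 rose and 5 fell with shRNA2 (HERC5, STAT2, ISG20, SAMD9L and SAMD9).

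Genes of secretory plasma cells fell in MM1.S: 13 of 30 fell and 6 rose with shRNA1, and 22 fell and HERPUD1 rose with shRNA2 (adjusted over the list alone, 14 and 6, then 22 and 3). The medians were -0.39 (camera adjusted p = 0.00627) and -0.71 (camera adjusted p = 3.6e-08), and the adjusted p with an estimated correlation was 0.191 and 0.0980. IRF4, a transcription factor on which myeloma cells depend, changed by -1.59 ± 0.12 (edgeR adjusted p = 8.8e-05) and -1.03 ± 0.12 (edgeR adjusted p = 5.5e-04). GPRC5D, an orphan receptor of plasma cells, changed by -3.13 ± 0.19 and -3.60 ± 0.20. PRDM1, which drives plasma cell differentiation, changed by -0.69 ± 0.11 and -0.86 ± 0.11, and XBP1, a regulator of the secretory machinery, by -0.77 ± 0.11 and -1.15 ± 0.11. In the unfolded protein response and ER chaperone list, 14 of 29 genes fell with shRNA1 while DNAJB9 and HERPUD1 rose, and 18 fell with shRNA2 while HERPUD1 rose (adjusted over the list alone, 16 and 18 fell). Its medians were -0.32 and -0.60 (camera adjusted p = 0.0236 and 2.6e-05), with an adjusted p of 0.191 and 0.0980 with an estimated correlation. PDIA4, an ER disulfide isomerase, changed by -0.92 ± 0.12 and -1.26 ± 0.12. A block on the replicate number brought the plasma cell identity genes lower with shRNA1 to 20 and those higher with shRNA2 to 3 (HERPUD1, CD27 and FCRL5), and in the unfolded protein response HERPUD1, DERL2 and DNAJB9 then rose with shRNA2.

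Cholesterol synthesis genes fell in MM1.S, 18 of 24 with shRNA1 (SC5D rose) and 16 with shRNA2, or 19 and 17 adjusted over the list alone. The medians were -0.89 and -0.75 (camera adjusted p = 7.3e-09 and 4.0e-06), and the adjusted p with an estimated correlation was 0.191 and 0.205. SQLE, an early enzyme of the sterol branch, changed by -1.57 ± 0.17 and -1.73 ± 0.17. In the glycolysis and hypoxia list, 14 of 29 fell with shRNA1 (BNIP3L and KDM3A rose) and 15 with shRNA2 (VEGFA rose), or 15 and 16 adjusted over the list alone. Its medians were -0.47 and -0.46 (camera adjusted p = 1.6e-04 and 2.8e-04), with an adjusted p of 0.327 and 0.463 with an estimated correlation. LDHA, which makes lactate, changed by -1.86 ± 0.15 and -1.81 ± 0.15. Among MYC targets in ribosome biogenesis, 28 of 39 fell with shRNA1 and 19 with shRNA2 (33 and 23 adjusted over the list alone), with medians of -0.58 and -0.49 (camera adjusted p = 2.7e-09 and 5.4e-04). With an estimated correlation the adjusted p was 0.206 and 0.515. LYAR, a nucleolar protein, fell by 1.55 ± 0.14 with each hairpin, whereas MYC gave 0.01 ± 0.16 with shRNA1 (edgeR adjusted p = 0.971) and fell by 1.10 ± 0.16 with shRNA2 (edgeR adjusted p = 0.00146). In the heat shock list, 13 of 18 fell with shRNA1, and 10 fell and DNAJB4 rose with shRNA2 (15 and 11 adjusted over the list alone). Its medians were -0.71 and -0.57 (camera adjusted p = 4.7e-04 and 0.00569), and the adjusted p with an estimated correlation was 0.327 and 0.552. A block on the replicate number brought the MYC targets lower with shRNA2 to 32 and WDR74 past the threshold as higher. In that fit BNIP3L, VEGFA, KDM3A and PFKM of the glycolysis list and DNAJB4 of the heat shock list rose with shRNA1. With shRNA2, ALDOC and VEGFA rose, and so did SC5D, TM7SF2 and PMVK of the cholesterol list.

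Cell death genes moved one by one in MM1.S. RIPK3, the kinase through which ZBP1 triggers necroptosis, rose by 0.76 ± 0.19 (edgeR adjusted p = 0.0181) and 0.84 ± 0.19 (edgeR adjusted p = 0.0121). The first call was lost without scramble replicate 1 (0.62, adjusted p = 0.0710) or shRNA1 replicate 2 (0.71, adjusted p = 0.0722), and the second without shRNA2 replicate 2 (0.77, adjusted p = 0.0765). RIPK1 rose by 0.66 ± 0.12 with shRNA1 and gave 0.13 ± 0.12 with shRNA2, and MLKL, the executor of necroptosis, gave 0.16 ± 0.15 and -0.42 ± 0.15 (edgeR adjusted p = 0.424 and 0.0666). The necroptosis and death receptor list did not pass (medians 0.22 and 0.13; camera adjusted p = 0.0616 and 0.453): 7 of 23 rose and PGAM5 fell with shRNA1, while RIPK3, SPATA2 and TNFRSF10B rose and CASP10, OTULIN and TNFRSF1A fell with shRNA2 (adjusted over the list alone, 6 and 1, then 3 and 3). BMF and BBC3 (PUMA), which promote apoptosis, rose by 2.23 ± 0.12 and 1.51 ± 0.26 with shRNA1 and by 1.21 ± 0.12 and 1.38 ± 0.26 with shRNA2. The BCL2 family rose as a list with shRNA1 (median 0.47, camera adjusted p = 6.2e-05, 0.191 with an estimated correlation), with 9 of 15 higher and BAD lower. With shRNA2 its median was 0.14 (camera adjusted p = 0.247), with 6 higher and 4 lower (BAK1, BID, BCL2 and BCL2L1); adjusted over the list alone the counts were the same. Among 30 p53 targets, 9 rose and 4 fell (DDB2, GADD45A and POLH among them) with shRNA1, and 7 rose and 6 fell with shRNA2 (10 and 5, then 8 and 6 adjusted over the list alone), and the list did not pass (medians 0.29 and 0.04; camera adjusted p = 0.116 and 0.247). CDKN1A (p21), a p53 target that stops the cell cycle, gave 0.51 ± 0.18 and 0.10 ± 0.18 (edgeR adjusted p = 0.0534 and 0.694), the former past the threshold in DESeq2 (0.52, adjusted p = 0.0198). With the replicate number as a block, CDKN1A passed with shRNA1 (edgeR adjusted p = 4.0e-05) and MLKL with shRNA2 (edgeR adjusted p = 0.0140). The necroptosis and p53 lists then passed as higher with shRNA1 (camera adjusted p = 0.00676 and 0.0439, and 0.385 and 0.438 with an estimated correlation). Both lists also passed with shRNA1 without a filter (camera adjusted p = 0.0183 and 0.0412), and the former with DESeq2 (0.0371). In the necroptosis list 12 rose and 6 fell with shRNA1 and 9 and 6 with shRNA2, and in the p53 list 16 and 8, then 12 and 9.

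Other lists split by hairpin in MM1.S. Of 26 NF-kB targets 18 rose and none fell with shRNA1 (19 and 1 adjusted over the list alone; median 1.14, camera adjusted p = 2.9e-10, and 0.191 with an estimated correlation). With shRNA2, 9 rose and 6 fell (10 and 7 adjusted over the list alone; median 0.22, camera adjusted p = 0.311). A block on the replicate number gave 20 higher and NFKBIB, SOD2 and CCL3 lower with shRNA1, and 12 higher and 9 lower with shRNA2. Of 21 genes of the B cell and germinal centre programme, 9 rose and MYBL1 and ETS1 fell with shRNA1, also adjusted over the list alone (median 0.74, camera adjusted p = 0.00488, and 0.422 with an estimated correlation). With shRNA2, BCL6, BACH2 and SPI1 rose and 11 fell (12 adjusted over the list alone; median -0.90, camera adjusted p = 0.0362, and 0.598 with an estimated correlation). Immediate early genes rose with shRNA1, 9 of 24 with FOSB and EGR1 lower (10 and 2 adjusted over the list alone; median 0.45, camera adjusted p = 0.0286, and 0.509 with an estimated correlation). They fell with shRNA2, 12 lower and NR4A2 higher (13 and 2 adjusted over the list alone; median -0.61, camera adjusted p = 0.00426, and 0.552 with an estimated correlation). Among 33 genes of the ATF4 and amino acid response, VLDLR rose and SHMT2, MTHFD2 and WARS fell with shRNA1, also adjusted over the list alone (median -0.34, camera adjusted p = 0.421). With shRNA2, SARS, VLDLR, DDIT3, SLC3A2 and GARS rose (none adjusted over the list alone; median 0.54, camera adjusted p = 0.00245, and 0.628 with an estimated correlation). These medians were -0.84 and 0.14 without scramble replicate 1, and 0.44 and 1.35 without scramble replicate 2. The count falling with shRNA1 was 22 without scramble replicate 1, and 14 rose without scramble replicate 2. With shRNA2, 26 rose without scramble replicate 2, none without shRNA2 replicate 1 and DDIT3 alone without shRNA2 replicate 2. Among 56 ribosomal protein genes, RPS27 rose and 5 fell (RPS16, RPL26, RPS20 and RPL28 among them) with shRNA1 (0 and 3 adjusted over the list alone; median -0.22, camera adjusted p = 0.0236, and 0.530 with an estimated correlation). With shRNA2, 8 rose, RPS27 among them (1 adjusted over the list alone; median 0.17, camera adjusted p = 0.0137, and 0.598 with an estimated correlation). The MHC class I list did not pass (medians -0.06 and -0.24; camera adjusted p = 0.954 and 0.112): 5 rose (HLA-F, HLA-B, NLRC5 and HLA-E among them) and 7 fell with shRNA1, and 2 rose (PSMB10 among them) and 7 fell with shRNA2 (6 and 7, then 2 and 7 adjusted over the list alone). With the replicate number as a block, the MHC class I list passed as lower with shRNA2, with 12 lower (camera adjusted p = 0.0397, and 0.682 with an estimated correlation), and 9 of its genes rose with shRNA1. In the same fit 15 B cell genes rose and 10 ATF4 response genes and 34 ribosomal protein genes fell with shRNA1, and 6 immediate early genes, 19 ATF4 response genes and 31 ribosomal protein genes rose with shRNA2. It also brought VLDLR, SLC7A11 and DDIT4 of the ATF4 list and RPS2 and RPS27 past the threshold as higher with shRNA1. With shRNA2, SLC7A5 and RPL3, RPL28, RPL35 and RPL32 were lower, and SPI1, BACH2, BCL6, HLA-DQA1 and S1PR2 of the B cell list higher. Reads of HLA, DDX60 and ribosomal protein genes may be shared with similar genes.

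Marker lists of other cell types and of each line checked for foreign RNA in MM1.S. Fibroblast and stromal markers passed with shRNA2, where SPARC, FBN1, FN1, PDGFRB and COL1A1 fell and TAGLN rose, also adjusted over the list alone (median -2.03, camera adjusted p = 0.00245, and 0.205 with an estimated correlation). With shRNA1, TAGLN and COL1A1 rose and SPARC fell (2 and 3 adjusted over the list alone; median -0.16, camera adjusted p = 0.961). T and NK cell markers (CD7 and IL7R higher with shRNA1; CD3E higher, GNLY and CD247 lower with shRNA2) had medians of 0.36 and 0.23 (camera adjusted p = 0.0616 and 0.966). Myeloid markers (ITGAM, FCER1G and CST3 higher with shRNA1; CST3 lower with shRNA2) had medians of 0.83 and 0.06 (camera adjusted p = 0.0616 and 0.966). MM1.S line markers (MAF, ITGB7 and CX3CR1 higher with shRNA1; IGLC2 and CCR1 lower with shRNA2) had medians of -0.02 and -0.35 (camera adjusted p = 0.421 and 0.469). H929 line markers (WHSC1, LETM1 and AUTS2 lower with shRNA1; WHSC1, AUTS2 and KLHL4 lower with shRNA2) had medians of -0.45 and -0.79 (camera adjusted p = 0.136 and 0.0605). Adjusted over the list alone, the counts of these 4 lists were the same, with 1 more H929 line marker higher with shRNA1. With the replicate number as a block, myeloid markers passed as higher with shRNA1 (camera adjusted p = 0.0439, and 0.401 with an estimated correlation) and H929 line markers as lower with shRNA2 (camera adjusted p = 0.0336, and 0.682 with an estimated correlation). In that fit SPARC, PDGFRB and FN1 fell, NUAK1 fell and KLHL4 rose with shRNA1, and with shRNA2 MAF rose and ITGB7, CCR1, CX3CR1, IGLC2 and IGLC3 fell. List members named here and below that fall outside the rule for named genes were chosen after their values were seen. In MM1.S the median had another sign than the mean or the test for fibroblast and MM1.S line markers with shRNA1, and for nucleic acid sensing, T and NK and myeloid genes with shRNA2. In H929 this held for NF-kB and p53 targets and MM1.S line markers with shRNA1, and for the BCL2 family, B cell and fibroblast lists with shRNA2.

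In H929, genes of DNA replication and mitosis were again lower with both hairpins, 48 and 50 of 50 DNA replication and G1/S genes and 62 of 62 G2/M and mitosis genes (adjusted p = 0.423 and 0.311 with an estimated correlation). Genes of ribosome biogenesis, of the ATF4 and amino acid response and of glycolysis also fell with both, with an adjusted p of 0.311 to 0.834 with an estimated correlation. Interferon-stimulated genes, higher in MM1.S (adjusted p = 0.191 and 0.0980 with an estimated correlation), were lower in H929 with shRNA1, where all 56 cytosolic ribosomal protein genes fell too (adjusted p = 0.540 and 0.423 with an estimated correlation). ST14, the membrane protease matriptase, rose by 3.81 ± 0.25 and 2.24 ± 0.25, and SPINT1, a protease inhibitor, by 2.94 ± 0.21 and 2.70 ± 0.21. Among 18213 genes tested with limma, 4685 were higher and 5044 lower with shRNA1, of which 1932 and 1808 by 2-fold or more. With shRNA2, 3274 were higher and 4551 lower, of which 936 and 1450 by 2-fold or more. The hairpins, each with its own controls, shared 1270 higher and 2104 lower genes, where independent lists would share 842 and 1260. Another 1453 genes moved in opposite directions, where independent lists would give 2077, and the fold changes had a Pearson correlation across genes of 0.281. Genes higher with shRNA2, and those shared, fell most without either shRNA2 library (ranges below). The scramble groups themselves differed in 5441 genes (limma adjusted p under 0.05; 3268 without replicate 2 of the scramble for shRNA1 and 3501 without replicate 2 of the scramble for shRNA2), so each H929 effect below depends on the scramble group it is set against. Against the other hairpin's scramble group, 3970 of the higher and 4359 of the lower genes kept their call with shRNA1 and 68 turned. With shRNA2, 1651 and 2671 kept theirs and 199 turned. The hairpins then shared 884 higher and 1295 lower genes, 627 and 965 of them also shared above, and SPINT1 gave 4.72 ± 0.21 and 0.92 ± 0.21.

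The 50 DNA replication and G1/S genes of H929 had medians of -2.02 with shRNA1 (camera adjusted p = 1.0e-18) and -1.67 with shRNA2 (camera adjusted p = 2.9e-22), and CCNE1 and CCNE2, cyclins of the S phase entry, did not pass with shRNA1. With an estimated correlation the adjusted p was 0.423 and 0.311. For the 62 G2/M and mitosis genes the medians were -3.04 (camera adjusted p = 6.3e-27) and -2.02 (camera adjusted p = 2.2e-26), again with an adjusted p of 0.423 and 0.311 with an estimated correlation. Both lists kept these counts when adjusted over the list alone. CDK1, the kinase that starts mitosis, changed by -3.48 ± 0.22 and -2.70 ± 0.22, BIRC5 by -3.58 ± 0.19 and -3.21 ± 0.19, and CENPA, the centromeric histone, by -3.69 ± 0.25 and -2.91 ± 0.25. Between the scramble groups, all 50 and all 62 genes were higher in the group for shRNA2 than in the group for shRNA1, with median differences of 1.27 and 1.35 (camera adjusted p = 1.4e-25 and 1.4e-27, and 0.234 with an estimated correlation for both lists). Against the other hairpin's scramble group, chosen after seeing the data, shRNA1 gave medians of -3.41 and -4.40 with all 50 and all 62 genes lower. On the same exchange shRNA2 gave medians of -0.46 and -0.60, with 26 of 50 genes lower and 1 higher, and 43 of 62 lower. CDK1, BIRC5 and CENPA then gave -1.31 ± 0.22, -2.02 ± 0.19 and -1.66 ± 0.25 with shRNA2.

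**Figure D2:**
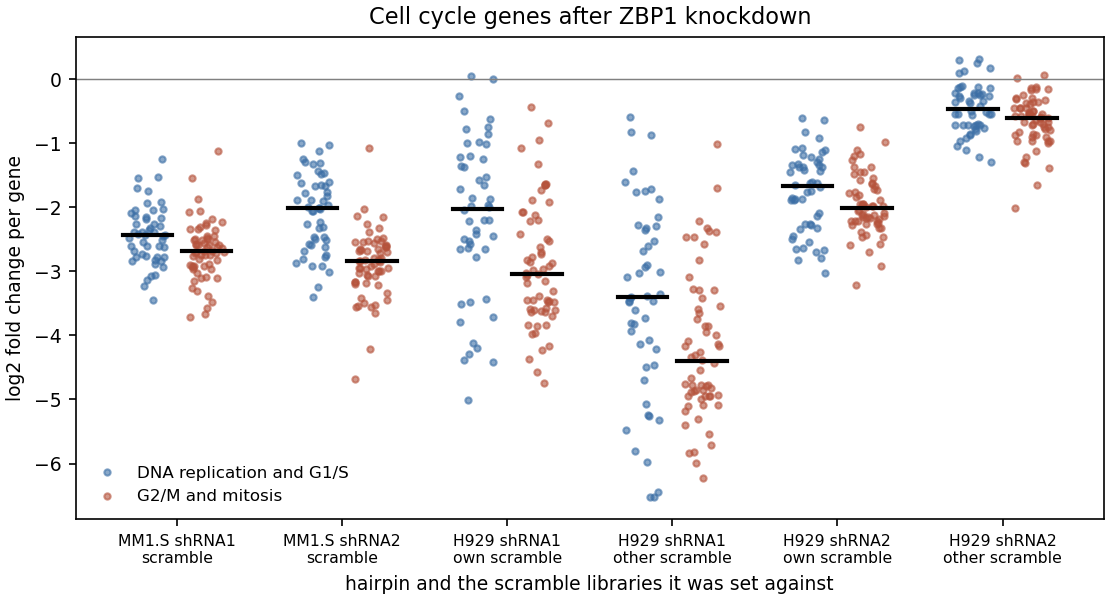
Log2 fold change (vertical axis) of each DNA replication and G1/S gene and each G2/M and mitosis gene, for each hairpin and each scramble group it was set against. Points are genes and black bars are list medians, which run from -2.01 to -2.84 in MM1.S and, in H929, from -0.46 with shRNA2 to -4.40 with shRNA1, both against the other hairpin's scramble group.

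Of 36 interferon-stimulated genes in H929, 27 fell and RSAD2 rose with shRNA1, the same counts when adjusted over the list alone, with a median of -1.31 (camera adjusted p = 2.05e-07, and 0.540 with an estimated correlation). IFI44L changed by -5.14 ± 0.22, IFI6 by -3.47 ± 0.11 and MX1 by -2.21 ± 0.17, all 3 induced by interferons. With shRNA2 the list did not pass (median -0.35, camera adjusted p = 0.421), with 16 lower and 7 higher, again the same adjusted over the list alone. The list was lower by a median of -1.13 in the scramble group for shRNA2 than in that for shRNA1, with 33 of 36 genes lower (camera adjusted p = 1.6e-14, and 0.234 with an estimated correlation). Against the other hairpin's scramble group, the median was -0.33 with shRNA1, with 16 genes lower and 10 higher, and -1.45 with shRNA2, with 31 lower and none higher; the list then passed with shRNA2 and not with shRNA1 (camera adjusted p = 1.1e-10 and 0.460, and 0.329 and 0.936 with an estimated correlation). IFI44L, IFI6 and MX1 then gave -3.41 ± 0.22, -1.75 ± 0.11 and -1.09 ± 0.17 with shRNA1. With all 4 scramble libraries as control it passed as lower with both hairpins, 23 of 36 lower with shRNA1 (median -0.91, camera adjusted p = 0.00226, and 0.756 with an estimated correlation) and 25 with shRNA2 (median -0.97, camera adjusted p = 2.5e-05, and 0.464 with an estimated correlation). Nucleic acid sensing genes did not pass as a list (medians -0.30 and -0.14; camera adjusted p = 0.147 and 0.464): of 24, TRAF6, TMEM173, TRAF3 and TBKBP1 rose and 11 fell with shRNA1, and TBKBP1, TRAF6 and IFIH1 rose and 8 fell with shRNA2, the same adjusted over the list alone. TMEM173 (STING) rose by 0.61 ± 0.11 with shRNA1 and fell by 1.00 ± 0.11 with shRNA2, and neither IRF3 (0.08 ± 0.09 and 0.03 ± 0.09; limma adjusted p = 0.502 and 0.797) nor TBK1 (-0.25 ± 0.11 and 0.05 ± 0.11; limma adjusted p = 0.0715 and 0.758) passed. The sensing list passed as lower with shRNA2 against the other scramble group (median -0.39, camera adjusted p = 0.00370, and 0.318 with an estimated correlation). There TMEM173 gave 1.12 ± 0.11 and -1.51 ± 0.11, and with shRNA1 IRF3 rose by 0.31 ± 0.09 and TBK1 fell by 0.28 ± 0.11 (limma adjusted p = 0.00756 and 0.0364).

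**Figure D3:**
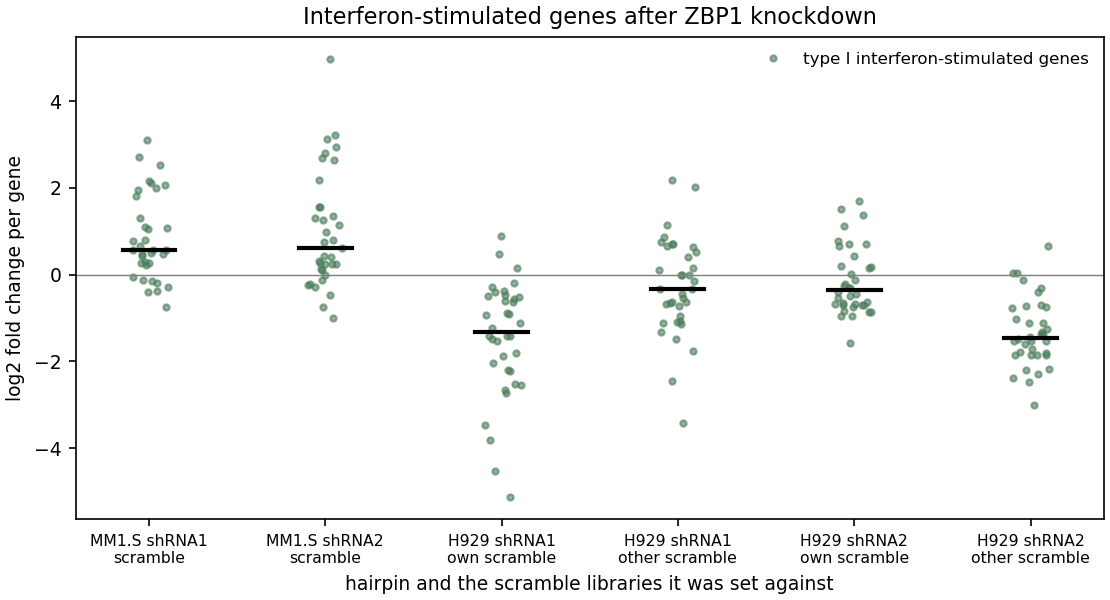
Log2 fold change (vertical axis) of each type I interferon-stimulated gene, for each hairpin and each scramble group it was set against. Points are genes and black bars are list medians, 0.56 and 0.61 in MM1.S; in H929 they are -1.31 and -0.35 against each hairpin's own scramble group and -0.33 and -1.45 against the other.

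Among MYC targets in ribosome biogenesis, 35 of 39 fell with each hairpin in H929 (35 and 37 adjusted over the list alone), with medians of -0.65 and -0.63 (camera adjusted p = 1.4e-08 and 1.8e-09). With an estimated correlation the adjusted p was 0.540 and 0.501. LYAR changed by -1.17 ± 0.12 and -1.30 ± 0.12, and MYC by -0.72 ± 0.11 and -1.19 ± 0.11 (limma adjusted p = 5.3e-05 and 5.9e-07). The list stood higher in the scramble group for shRNA2 than in that for shRNA1, by a median of 0.55 with 33 of 39 genes higher (camera adjusted p = 3.7e-12, and 0.234 with an estimated correlation). Against the other scramble group all 39 fell with shRNA1 (median -1.15, camera adjusted p = 3.5e-12, and 0.365 with an estimated correlation), but the list did not pass with shRNA2 (median -0.08, 6 lower, camera adjusted p = 0.589), where LYAR gave -0.52 ± 0.12 (-1.95 ± 0.12 with shRNA1). With all 4 scramble libraries as control, 27 fell with shRNA2 (median -0.35, camera adjusted p = 2.8e-05, and 0.464 with an estimated correlation). In the ATF4 and amino acid response list, 26 of 33 fell with shRNA1 while ATF3, VLDLR and DDIT3 rose, and 27 fell with shRNA2 (26 and 28 adjusted over the list alone). Its medians were -0.97 and -0.62 (camera adjusted p = 6.5e-07 for each), with an adjusted p of 0.423 and 0.311 with an estimated correlation. PHGDH, the first enzyme of serine synthesis, changed by -2.76 ± 0.13 and -1.36 ± 0.13, and SHMT2, which moves serine carbon into folate, by -2.28 ± 0.08 and -0.86 ± 0.08. This list too stood higher in the scramble group for shRNA2, by a median of 0.46 with 24 of 33 genes higher (camera adjusted p = 5.5e-07, and 0.234 with an estimated correlation). Against the other scramble group its medians were -1.34 with shRNA1, with 30 lower (camera adjusted p = 3.4e-08, and 0.317 with an estimated correlation), and -0.13 with shRNA2, with 10 lower, where it did not pass (camera adjusted p = 0.117). PHGDH then gave -0.30 ± 0.13 with shRNA2 (limma adjusted p = 0.0807) and SHMT2 -0.34 ± 0.08. With all 4 as control, 20 fell with shRNA2 (median -0.39, camera adjusted p = 1.2e-04, and 0.418 with an estimated correlation). In the glycolysis and hypoxia list, 15 of 28 fell and 5 rose (KDM3A, EGLN3, VEGFA, PFKL and PDK1) with shRNA1, and 19 fell and 2 rose (ALDOC and VEGFA) with shRNA2. When adjusted over the list alone, 15 and 22 fell. Its medians were -0.53 and -0.50 (camera adjusted p = 0.0309 and 0.00142), and the adjusted p with an estimated correlation was 0.722 and 0.834. HK2, the first enzyme of glycolysis, changed by -1.15 ± 0.11 and -1.36 ± 0.11. The shRNA2 median of the list was -0.30 against the other scramble group (15 lower, camera adjusted p = 0.0143, and 0.613 with an estimated correlation), with HK2 at -0.82 ± 0.11. All 56 cytosolic ribosomal protein genes fell with shRNA1, also adjusted over the list alone (median -1.14, camera adjusted p = 1.7e-23, and 0.423 with an estimated correlation). With shRNA2, 9 fell and 2 rose (RPS20 and RPL30; 7 and 1 adjusted over the list alone), and the list did not pass (median -0.03, camera adjusted p = 0.795). It passed as higher with shRNA2 against the other scramble group, with 38 higher (median 0.33, camera adjusted p = 2.8e-08, and 0.438 with an estimated correlation), and against all 4, with 22 higher (median 0.12, camera adjusted p = 0.00276, and 0.620 with an estimated correlation).

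Plasma cell identity genes of H929 fell with shRNA2, 17 of 29, also adjusted over the list alone (median -0.52, camera adjusted p = 7.8e-04, and 0.311 with an estimated correlation). With shRNA1 the list did not pass (median -0.05, camera adjusted p = 0.630), with 10 higher and 12 lower, again adjusted over the list alone. IRF4 fell by 0.63 ± 0.10 with shRNA2 (limma adjusted p = 1.1e-04). With shRNA1 it rose by 0.30 ± 0.10 (limma adjusted p = 0.0198), a call lost without replicate 2 of the scramble group for shRNA1 (0.24, adjusted p = 0.129) or shRNA1 replicate 1 (0.15, adjusted p = 0.226). PRDM1 rose by 0.61 ± 0.09 with shRNA1 and fell by 0.57 ± 0.09 with shRNA2, and XBP1 changed by -0.59 ± 0.09 and -0.64 ± 0.09. Of 29 genes of the unfolded protein response, 19 fell and SYVN1 rose with shRNA2, also adjusted over the list alone (median -0.39, camera adjusted p = 1.1e-04, and 0.311 with an estimated correlation). With shRNA1, 12 rose and 8 fell, also adjusted over the list alone, and the list did not pass (median 0.11, camera adjusted p = 0.390). Among the death genes, MLKL fell by 0.63 ± 0.11 with shRNA1 (limma adjusted p = 1.5e-04) and gave -0.08 ± 0.11 with shRNA2 (limma adjusted p = 0.559), and RIPK1 rose by 0.83 ± 0.13 with shRNA1 and gave -0.03 ± 0.13 with shRNA2. RIPK3 had 0 of 144809602 reads in the 8 H929 libraries, which allows up to 0.0207 CPM. The necroptosis list did not pass (medians 0.03 and -0.05; camera adjusted p = 0.630 and 0.799), with 9 of 22 higher and 6 lower with shRNA1, and SPATA2 and FAS higher and PGAM5, TNFRSF10A, TRAF2, CASP10 and CFLAR lower with shRNA2, also adjusted over the list alone. BMF rose by 1.01 ± 0.08 and 1.08 ± 0.08 in H929. The BCL2 family rose as a list with shRNA1, 10 of 16 higher and BAD lower (median 0.64, camera adjusted p = 0.00636, and 0.449 with an estimated correlation). With shRNA2, BMF, BBC3, BCL2L11, BCL2L1 and BAD rose and BID, BAK1, BIK, BCL2 and PMAIP1 fell (median 0.01, camera adjusted p = 0.826), the same adjusted over the list alone. Against the other scramble group the median of the unfolded protein response was -0.26 with shRNA2 (camera adjusted p = 0.00126, and 0.318 with an estimated correlation), and that of the BCL2 family 1.00 with shRNA1 (camera adjusted p = 0.0133, and 0.365 with an estimated correlation). The exchange turned the medians of plasma cell identity (0.097) and the unfolded protein response (-0.022) with shRNA1 and of the BCL2 family with shRNA2 (-0.10), and none of these passed. IRF4 gave -0.06 ± 0.10 with shRNA1 (limma adjusted p = 0.632) and -0.28 ± 0.10 with shRNA2, XBP1 -0.41 ± 0.09 with shRNA2, and BMF 1.65 ± 0.08 and 0.45 ± 0.08.

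Immediate early genes of H929 moved in opposite directions with the hairpins: 18 of 25 rose and EGR1, DUSP6 and FOSB fell with shRNA1 (18 and 4 adjusted over the list alone; median 0.66, camera adjusted p = 0.00109, and 0.540 with an estimated correlation). With shRNA2, DUSP5 rose and 18 fell, also adjusted over the list alone (median -0.65, camera adjusted p = 1.4e-04, and 0.489 with an estimated correlation). B cell and germinal centre genes rose with shRNA1, 15 of 24 with SPI1 and MYBL1 lower, also adjusted over the list alone (median 1.12, camera adjusted p = 0.00214, and 0.423 with an estimated correlation). They did not pass with shRNA2 (6 higher and 7 lower, 6 and 8 adjusted over the list alone; median 0.14, camera adjusted p = 0.795). MHC class I genes fell with shRNA2, 13 of 20 with NLRC5 higher (13 and 3 adjusted over the list alone; median -0.39, camera adjusted p = 0.00805, and 0.677 with an estimated correlation). With shRNA1, 8 fell and CALR, NLRC5 and TAP2 rose (10 and 3 adjusted over the list alone; median -0.20, camera adjusted p = 0.231). The G1 cyclin list passed with shRNA2, 12 of 28 lower and CDKN1B, CDKN2D, TFDP2, RBL2 and CDKN1C higher, also adjusted over the list alone (median -0.24, camera adjusted p = 0.0493, and 0.311 with an estimated correlation). It did not pass with shRNA1 (7 higher and 12 lower, 8 and 12 adjusted over the list alone; median -0.10, camera adjusted p = 0.630). Of 23 NF-kB targets, BIRC3, TNFAIP2, NFKBIA, CD74 and RELB rose and ICAM1, TNFAIP3, TNIP1 and NFKB2 fell with shRNA1. With shRNA2, NFKB2, CD40 and REL rose and 8 fell (4 and 4, then 3 and 8 adjusted over the list alone; medians -0.08 and -0.11, camera adjusted p = 0.996 and 0.421). Of 29 p53 targets, 8 rose and 9 fell with shRNA1, and 10 rose and PLK3, GADD45A and DDB2 fell with shRNA2, also adjusted over the list alone (medians -0.06 and 0.09; camera adjusted p = 0.907 and 0.0827). Of 18 heat shock genes, DNAJB4, HSPA1B and DNAJB1 rose and 8 fell with shRNA1, and DNAJB4 rose and 8 fell with shRNA2, also adjusted over the list alone (medians -0.32 and -0.40; camera adjusted p = 0.390 and 0.0781). Against the other scramble group, medians with shRNA1 were 1.14 for immediate early genes, 1.94 for B cell genes and -0.86 for heat shock genes, and all 3 lists passed (camera adjusted p = 2.0e-04, 1.0e-04 and 0.0247, and 0.383, 0.317 and 0.745 with an estimated correlation). With shRNA2, MHC class I and NF-kB lists were lower (medians -0.62 and -0.67; camera adjusted p = 4.4e-06 and 0.00104, and 0.318 for each with an estimated correlation), and the G1 cyclin list did not pass (median -0.014, camera adjusted p = 0.418). With all 4 as control the NF-kB list passed with shRNA2 (median -0.31, camera adjusted p = 0.0169, and 0.418 with an estimated correlation) and the G1 cyclin list did not (camera adjusted p = 0.0600). The exchange turned the median to 0.24 for heat shock genes with shRNA2 (7 higher, camera adjusted p = 0.114) and to 0.14 for MHC class I genes with shRNA1 (9 higher, camera adjusted p = 0.621). It also turned the medians of NF-kB (0.11) and p53 targets (0.058) with shRNA1 and of p53 targets (-0.031) and B cell genes (-0.49) with shRNA2, none of which passed. Against its own scramble group the heat shock list passed with shRNA2 in DESeq2, without a filter, with the compared groups alone and in edgeR on recovered reads (camera adjusted p = 0.0484, 0.00702, 0.0154 and 0.0470).

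Marker lists in H929 did not pass with either hairpin against its own scramble group in limma, though fibroblast markers passed with shRNA1 in DESeq2 and in edgeR on recovered reads (camera adjusted p = 0.0409 and 0.0261). T and NK cell markers had medians of -0.89 and -0.46 (camera adjusted p = 0.231 and 0.799), with TRAC, PRF1, GNLY and CD4 lower with shRNA1, and CD3E and ZAP70 higher and GZMB, PRF1 and GNLY lower with shRNA2. Myeloid markers had medians of -0.74 and -0.34 (camera adjusted p = 0.223 and 0.421), with CST3 higher and S100A9, CD33 and FCER1G lower with shRNA1. LYZ was higher and S100A9, CSF1R, CD14 and CST3 lower with shRNA2. Fibroblast markers had medians of 0.26 and 0.24 (camera adjusted p = 0.283 and 0.847), with COL1A1, COL6A2, COL6A1 and PDGFRA higher and TAGLN and ACTA2 lower with shRNA1. ACTA2 and TAGLN were higher and COL6A1, FN1 and COL1A1 lower with shRNA2. Epithelial and kidney markers, too few to test in MM1.S, had medians of 0.05 and -0.12 (camera adjusted p = 0.630 and 0.795), with KRT8 and KRT18 higher with shRNA1 and KRT18 lower with shRNA2. MM1.S line markers had medians of 0.09 and -0.02 (camera adjusted p = 0.907 and 0.795), with MAF and NUAK1 higher and CCR1 and ITGB7 lower with shRNA1, and ITGB7 and CCR1 lower with shRNA2. H929 line markers had medians of 0.03 and -0.44 (camera adjusted p = 0.681 and 0.795), with AUTS2 and KLHL4 higher and FGFR3 and LETM1 lower with shRNA1. FGFR3 and WHSC1 were higher and LETM1, MYRF and IGKC lower with shRNA2. Adjusted over the list alone, the counts were the same, with 1 more T and NK marker lower with shRNA2 and 1 more fibroblast marker lower with shRNA1. Against the other scramble group, fibroblast markers passed as higher with shRNA1 (median 0.37, camera adjusted p = 0.0324, and 0.317 with an estimated correlation). The median of myeloid markers turned to 0.18 with shRNA1 (camera adjusted p = 0.946). Fibroblast and myeloid markers then passed as lower with shRNA2 (medians -0.49 and -0.83; camera adjusted p = 0.0243 and 0.0243, and 0.318 with an estimated correlation for both lists).

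**Figure D4:**
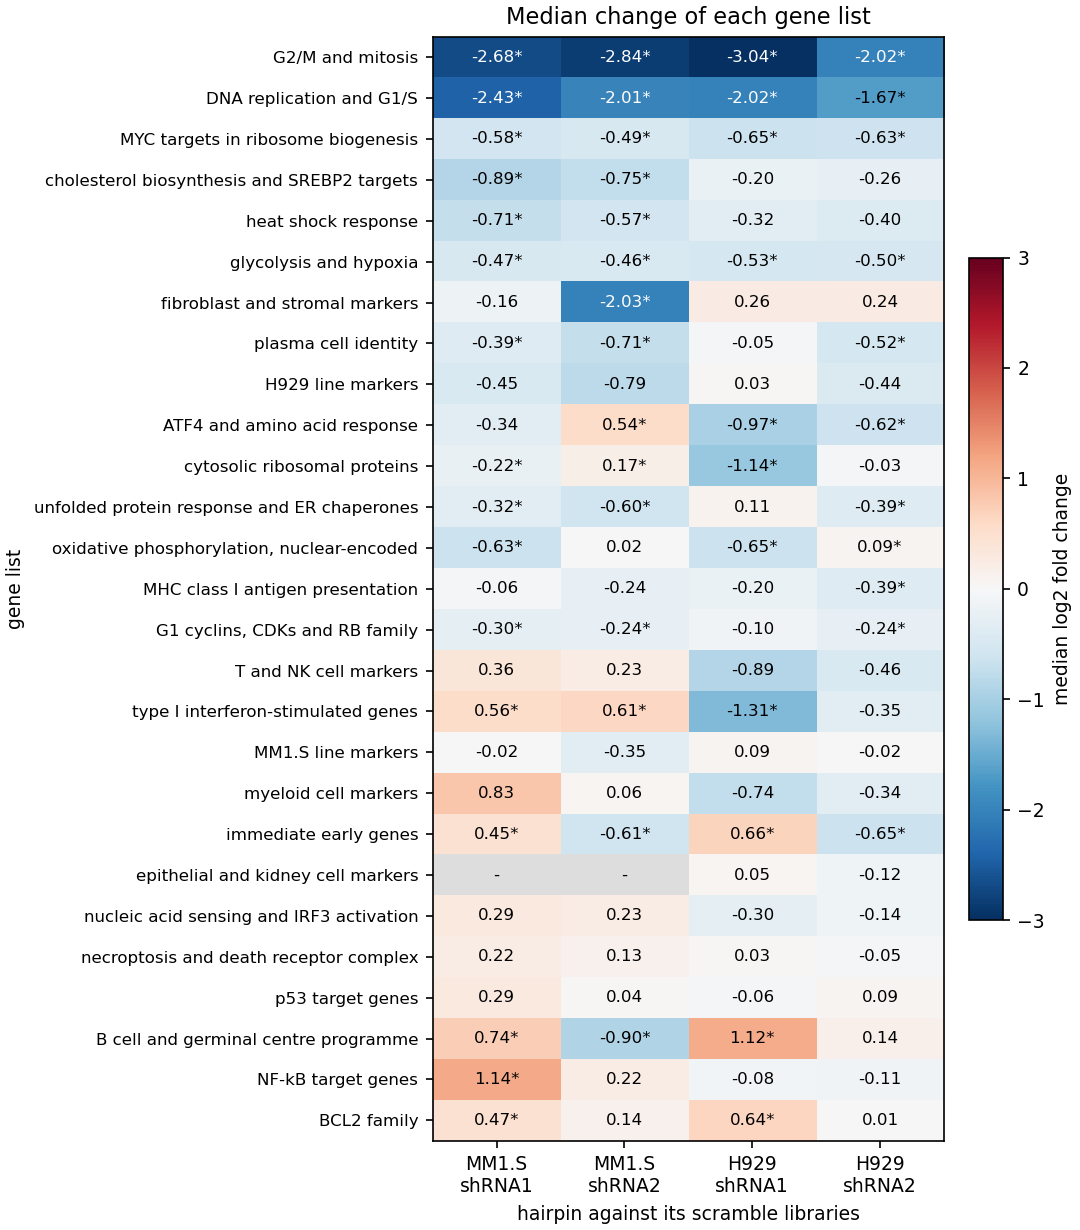
Median log2 fold change of each of the 27 gene lists (vertical axis) in each hairpin comparison (horizontal axis), printed in each cell and shown by colour. An asterisk marks a camera adjusted p under 0.05 with the preset correlation; the G2/M and mitosis medians are -2.68, -2.84, -3.04 and -2.02, and a dash marks a list with under 5 measured genes.

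Across both lines and both hairpins, 366 genes were higher and 988 lower in all 4 comparisons (227 higher without MM1.S shRNA2 replicate 1, and 637 with the replicate number as a block). With the H929 scramble groups exchanged, 253 and 552 were, 215 and 462 of them the same genes. Those lower included BIRC5, CDK1, MYBL2, a transcription factor of cycling cells, and UHRF1, which maintains DNA methylation; UHRF1 changed by -3.14 ± 0.28 and -2.69 ± 0.27 in MM1.S and by -4.29 ± 0.26 and -2.79 ± 0.26 in H929. Against the other scramble group UHRF1 gave -6.52 ± 0.26 with shRNA1 and did not pass with shRNA2 (-0.56 ± 0.26, limma adjusted p = 0.0976), where MYBL2 gave -1.22 ± 0.15. Those higher included PLEKHA1, which binds phosphoinositides, at 2.56 ± 0.22 and 2.66 ± 0.22 in MM1.S and 2.37 ± 0.23 and 1.53 ± 0.23 in H929. CTSF, a lysosomal cysteine protease, rose by 1.70 ± 0.13 and 1.70 ± 0.13 in MM1.S and by 1.66 ± 0.11 and 1.56 ± 0.11 in H929, but there gave 3.08 ± 0.11 and 0.14 ± 0.11 (limma adjusted p = 0.350 with shRNA2) against the other scramble group. GALC, a lysosomal galactosidase, rose by 2.85 ± 0.30 and 2.88 ± 0.30, then 1.06 ± 0.12 and 1.27 ± 0.12, and ZBTB18, a transcriptional repressor, by 2.48 ± 0.12 and 1.42 ± 0.12, then 1.80 ± 0.11 and 1.11 ± 0.11. Fold changes correlated across genes between the lines with the same hairpin (Pearson 0.527 for shRNA1 and 0.632 for shRNA2), and less closely between different hairpins (0.357 for MM1.S shRNA1 against H929 shRNA2, and 0.164 for MM1.S shRNA2 against H929 shRNA1). These pairs share no libraries, and the difference between the correlations was not tested.

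The hairpins also differed from each other. In MM1.S, 6559 genes differed between shRNA2 and shRNA1 in edgeR (4287 without shRNA1 replicate 1, 3858 without shRNA2 replicate 1, 3708 without shRNA2 replicate 2, and 10380 with the replicate number as a block), and in H929 the hairpins' effects differed in 7618 genes in limma. Nuclear-encoded genes of oxidative phosphorylation were higher with shRNA2 than with shRNA1 in both lines, 43 of 55 in MM1.S (median difference 0.65, camera adjusted p = 4.2e-13, and 0.357 with an estimated correlation). In H929, 46 of 55 were (0.71, camera adjusted p = 3.8e-13, and 0.474 with an estimated correlation). With shRNA1, 39 fell in MM1.S (43 adjusted over the list alone; median -0.63, camera adjusted p = 6.4e-09, and 0.191 with an estimated correlation). In H929, 47 did (49 adjusted over the list alone; median -0.65, camera adjusted p = 3.1e-11, and 0.423 with an estimated correlation). With shRNA2, 7 rose and 6 fell in MM1.S (6 and 6 adjusted over the list alone; median 0.02, camera adjusted p = 0.311), and with the replicate number as a block 20 rose and 15 fell, and NDUFB5 and NDUFA13 rose with shRNA1. In H929, 12 rose and 5 fell (NDUFS8, ATP5B, NDUFB10, UQCRH and ATP5G1; 11 and 5 adjusted over the list alone; median 0.09, camera adjusted p = 0.0493, and 0.837 with an estimated correlation). Against the other H929 scramble group 44 rose with shRNA2 (median 0.39, camera adjusted p = 8.2e-11, and 0.318 with an estimated correlation). In H929 the shares of mitochondrial reads given above differed the same way between the hairpins. Immediate early genes were lower with shRNA2 than with shRNA1, 16 of 24 in MM1.S (-1.20, camera adjusted p = 8.7e-08, and 0.369 with an estimated correlation). In H929, 21 of 25 were (-1.08, camera adjusted p = 6.5e-08, and 0.474 with an estimated correlation). The transcription factor gene FOS was lower with shRNA2 than with shRNA1 by -6.79 ± 0.33 in MM1.S and -5.23 ± 0.65 in H929 (edgeR and limma adjusted p = 4.7e-05 and 9.7e-06). All 56 cytosolic ribosomal protein genes were higher in the shRNA2 effect of H929 (1.10, camera adjusted p = 3.0e-24, and 0.480 with an estimated correlation). NF-kB targets were lower with shRNA2 in MM1.S (17 of 26; -1.06, camera adjusted p = 3.1e-08, and 0.357 with an estimated correlation). BCL7A, a chromatin remodelling subunit, was higher with shRNA2 than with shRNA1 by 2.87 ± 0.22 in MM1.S (edgeR adjusted p = 1.5e-04). In H929, the effect on IFI44L differed between the hairpins by 5.83 ± 0.30 (limma adjusted p = 1.6e-09). Each H929 difference here sets a hairpin against its own scramble group, so it includes the difference between those groups. They differed in 5441 genes, and by a median of -1.13 over the interferon-stimulated genes.

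The difference between the lines was tested for each hairpin over 20370 genes in limma: 4366 genes differed with shRNA1 and 1987 with shRNA2, 806 of them in the same direction with both. Differences are the hairpin's effect in MM1.S minus its effect in H929, not levels. For interferon-stimulated genes the effect in MM1.S exceeded that in H929 by a median of 1.71 with shRNA1 (23 of 36 higher, camera adjusted p = 1.1e-17, and 0.106 with an estimated correlation). With shRNA2 the median was 0.92 (16 higher, camera adjusted p = 2.9e-10, and 0.343 with an estimated correlation). MX1 differed by 4.01 ± 0.26 and 2.31 ± 0.26 (limma adjusted p = 2.0e-06 and 2.8e-04), and ABCG1 by 4.68 ± 0.28 and 3.37 ± 0.28 (limma adjusted p = 1.2e-06 and 3.3e-05). For cholesterol synthesis genes the effect differed by a median of -0.83 with shRNA1 (13 of 24 lower, camera adjusted p = 3.3e-07, and 0.0851 with an estimated correlation). With shRNA2 this was -0.59 (9 lower, camera adjusted p = 1.4e-06, and 0.216 with an estimated correlation). For 56 ribosomal protein genes the effect exceeded that in H929 by a median of 0.99 with shRNA1 (all 56 higher, camera adjusted p = 4.3e-30, and 0.0851 with an estimated correlation). With shRNA2 the median was 0.23 (RPL3, RPS2, RPS27 and RPL10A higher, camera adjusted p = 3.1e-05, and 0.532 with an estimated correlation). For 62 G2/M and mitosis genes it was -0.88 with shRNA2 (27 lower, camera adjusted p = 5.5e-19, and 0.317 with an estimated correlation). With shRNA1 it was 0.21, with 14 higher and 11 lower, and the list did not pass (camera adjusted p = 0.315). The H929 median of this list with shRNA2 was -2.02, or -0.60 against the other scramble group. For the 33 ATF4 response genes the differences were 0.72 and 1.29 (12 higher and ATF3 lower, then 18 higher, with camera adjusted p = 7.5e-04 and 1.2e-12, and 0.660 and 0.413 with an estimated correlation). Without 1 MM1.S scramble library, the MM1.S medians of the ATF4 list were -0.84 or 0.44 with shRNA1, and 0.14 or 1.35 with shRNA2. NF-kB targets had 0.93 and 0.36 (16 and 7 of 27 higher; camera adjusted p = 1.3e-05 and 0.0220, and 0.0851 and 0.342 with an estimated correlation). The unfolded protein response, sensing, T and NK, DNA replication, G1 cyclin and heat shock lists also passed with shRNA1, and the plasma cell, DNA replication, fibroblast, B cell and MYC target lists with shRNA2. Their adjusted p was 3.6e-04 to 0.0405, and 0.0851 to 0.771 with an estimated correlation. All these differences use each hairpin's own H929 scramble group. Against the other group, H929 medians with shRNA2 were 0.33 for ribosomal protein genes and -0.08 for MYC targets (0.17 and -0.49 in MM1.S). For DNA replication genes with shRNA1 the H929 median was -3.41 (-2.43 in MM1.S). The median differences above were 0.23, 0.19 and -0.29, so their direction may depend on the scramble group, which was not tested. In H929 alone the cholesterol list did not pass, with 5 higher (SC5D, HMGCS1 and MVD among them) and 11 lower with shRNA1, and TM7SF2, MSMO1 and FDFT1 higher and 10 lower with shRNA2, or 5 and 11, then 3 and 11, adjusted over the list alone (medians -0.20 and -0.26; camera adjusted p = 0.359 and 0.105). HES6, a transcriptional regulator of differentiation, differed by -4.18 ± 0.33 and -2.04 ± 0.33, and ST14 by -3.07 ± 0.24 and -2.62 ± 0.24. The shRNA2 and shared gene counts were lower without some single libraries, as given below.

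The authors' deposited tables of the same 4 comparisons gave log2 fold changes that correlated with these across genes (Pearson 0.960, 0.956, 0.977 and 0.976; Spearman 0.993, 0.992, 0.989 and 0.993, in the order MM1.S shRNA1 and shRNA2, then H929 shRNA1 and shRNA2). They called 3674, 3637, 3649 and 1908 genes higher and 4528, 4486, 4003 and 3539 lower, held 90.3%, 90.1%, 78.1% and 69.5% of the calls made here, and called none in the opposite direction. ZBP1 in those tables was -2.54, -3.07, -1.24 and -1.60.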

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

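The tests against the other H929 scramble group, the restriction of the word search to genes without or with an Alu stretch, the interferon list without each MM1.S library and the list tests of the line difference were chosen after results had been seen. A limma test of the difference in hairpin effect between the lines singled out 4366 genes with shRNA1 and 1987 with shRNA2, 806 in the same direction with both. The shRNA2 count was 1063 and 1018 without replicate 1 or 2 of its H929 scramble group, 836 and 823 without H929 shRNA2 replicate 1 or 2, and 1208 without MM1.S shRNA2 replicate 1; without the same 4 H929 libraries the shared count was 453, 461, 383 and 382. Effects in MM1.S exceeded those in H929 (shRNA1, then shRNA2) for MX1 (4.01 and 2.31), ABCG1 (4.68 and 3.37), DDX60 (4.97 and 3.20), XAF1 (5.40 and 2.82) and CHAC1 (2.91 and 3.18). Effects in MM1.S were below those in H929 for AHNAK (-5.57 and -3.44), PXDN (-6.03 and -2.08), ST8SIA2 (-3.78 and -2.58), HES6 (-4.18 and -2.04) and ST14 (-3.07 and -2.62). The CHAC1 call with shRNA1 was lost without any H929 library compared (2.71, 3.11, 2.66 and 3.16, scramble then shRNA1) or either MM1.S shRNA1 library (2.98 and 2.86), and with shRNA2 without any H929 library compared (3.21, 3.15, 3.16 and 3.21) or either MM1.S shRNA2 library (3.17 and 3.20). The PXDN call with shRNA2 was lost without any H929 library compared (-2.06, -2.11, -1.83 and -2.34), MM1.S scramble replicate 1 (-2.06) or MM1.S shRNA2 replicate 1 (-1.83). Interferon-stimulated genes differed by a median of 1.71 with shRNA1 and 0.92 with shRNA2 (camera adjusted p with an estimated correlation 0.106 and 0.343).

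Interferon-stimulated genes were higher in MM1.S and lower in H929 with shRNA1 (adjusted p with an estimated correlation 0.191 and 0.0980 in MM1.S and 0.540 in H929). Dependence on 1 MM1.S library is argued against: the lowest median without a library was 0.57. The level of the H929 scramble group for shRNA1 may account for part of the H929 fall: against the other scramble group the median was -0.33 with members moving both ways, which cannot tell it apart from an effect of the hairpin. A biological difference between the lines in how ZBP1 acts on interferon signalling stays open and untested.

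DNA replication and mitosis genes were lower with both hairpins in both lines (adjusted p with an estimated correlation 0.0980 to 0.423). A trend on GC content or transcript length is argued against as the whole cause, since the highest of the 4 medians after removing it was -1.84. The level of the H929 scramble group is argued against for shRNA1 (-3.98 against the other group). For shRNA2 the median of the 112 genes against the other group was -0.55, with an SD of 0.40, so part of that fall may come from the scramble level and the explanations cannot be told apart. Slower proliferation after ZBP1 loss stays open as a biological explanation, and no growth data are among these tables.

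The effects of shRNA1 and shRNA2 differed within each line. GC content and transcript length are argued against, since 97.7% of the correlation of the hairpin difference between the lines was kept after the trend was removed. Of 15646 words of 7 bases in 3' UTRs, ATCAACA scored highest in both lines (9.14 in MM1.S and 7.47 in H929, above the highest of 100 shuffles, 4.35 and 4.20), is present in ZBP1 itself (as are 25.0% of the words) and so fits a seed of shRNA2; off-target repression by shRNA2 may add to the difference. Genes with the word were lower more often than others with shRNA2 (39.2% against 24.7% in MM1.S, 45.3% against 30.2% in H929) and less often with shRNA1 (19.8% against 25.3%, and 23.8% against 33.8%). Part of the score may thus come from shRNA1. These shares were not tested or corrected for 3' UTR length, as the scores were, so they cannot settle this. Among the genes lower in all 4 comparisons 7.88% carried the word, against 8.01% of all genes searched. For shRNA1 the lowest word, TCGAGAC, scored -7.62 and -5.77 but -1.68 and -0.0608 without genes that carry an Alu stretch, where 113 of its 681 genes are left, and -4.68 and -3.19 among the 2055 genes that carry one, so its seed cannot be told apart from a repeat effect; the hairpin sequences are not in the labels.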

How the results depend on the processing

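Fits added after the data were seen were edgeR on recovered H929 reads, a pseudocount of 5 and limma for MM1.S. ZBP1 was lower and past its threshold under each alternative run, with log2 fold changes of -2.64 to -2.40 and -3.25 to -2.97 in MM1.S and of -1.40 to -1.16 and -1.76 to -1.54 in H929, and of -1.02 ± 0.09 and -1.91 ± 0.09 there against the other hairpin's scramble group. Of 780 values of named genes, 772 kept direction and side of the threshold with the other scaling (median-of-ratios in MM1.S, TMM in H929), 751 with DESeq2 (26 lost the threshold, 3 gained it) and 723 without a filter (40 lost, 17 gained); 125 of 637 called values were lost without at least 1 library. With all 4 H929 scramble libraries as control, 8 values reversed: with shRNA1 CDKN1A 0.17 and KLF2 0.41, and with shRNA2 CDKN1A -0.49, XAF1 -0.63, IFI44L -0.16, CDKN1C -0.26, TAGLN -0.056 and COL6A2 -0.60; the line difference with shRNA2 then counted 3102 genes. Against the other hairpin's H929 scramble group, of 186 values with shRNA1 7 lost the threshold and 9 gained it, and 12 turned in direction with a call in at least 1 of the 2; with shRNA2 26 lost it, 9 gained it and 33 turned. Without MM1.S scramble replicate 2, PSAT1 (0.73) and CHAC1 (1.68) reversed with MM1.S shRNA1, in ranges from -1.15 and -1.45. The replicate number as a block gave 5068 higher and 5513 lower with MM1.S shRNA1, 4779 higher with shRNA2, 2412 and 3336 with both, 637 higher in both lines and 10380 between the hairpins; of the 780 values it brought 48 past the threshold, IRF3, TBK1, CDKN1A and MLKL in MM1.S among them, and took 2 off it (SPATA2 and RRM2B with H929 shRNA1). Without a filter the line difference counted 1201 genes with shRNA2 and 475 with both. With an estimated correlation 0 lists moved in either line. Under fry 11 moved in MM1.S and 10 in H929, all main ones among them. The G2/M fry adjusted p was 2.4e-04 to 0.00217. The G1 cyclin call with H929 shRNA2 was lost with TMM scaling (camera adjusted p = 0.0512), the compared groups alone (0.102), the block (0.0623) and a pseudocount of 5 (0.0536), and the oxidative phosphorylation call there without a filter (0.0748), with the compared groups alone (0.0722), the block (0.0623) and a pseudocount of 5 (0.0540). The B cell call with MM1.S shRNA2 was lost with the compared groups alone (0.0650) and with limma (0.0506). Camera calls gained with DESeq2 were the MM1.S shRNA1 necroptosis (0.0371) and myeloid lists (0.0309; 0.0447 with the compared groups alone), H929 shRNA1 fibroblast markers (0.0409; 0.0261 in edgeR) and, with H929 shRNA2, p53 targets (0.0263; 0.0289 in edgeR) and heat shock genes (0.0484; 0.0154 with the compared groups alone, 0.0470 in edgeR). Gained without a filter were, in MM1.S, nucleic acid sensing (0.0494), necroptosis (0.0183), p53 (0.0412) and T and NK lists (0.0192) with shRNA1 and MHC class I (0.0138) and H929 line markers (0.0191; 0.0461 in limma) with shRNA2. In H929 these were nucleic acid sensing with shRNA1 (0.0281), and cholesterol synthesis (0.0219) and heat shock genes (0.00702) with shRNA2. The fry test gained 23 list calls and lost 4 (MM1.S shRNA1 immediate early, MM1.S shRNA2 ATF4 and ribosomal protein, and H929 shRNA2 oxidative phosphorylation genes). Without 1 library, with the lone library assumed to vary like the other groups, counts ranged over 2092 to 3307 (MM1.S shRNA1 lower), 1304 to 2166 and 2312 to 3548 (MM1.S shRNA2 higher and lower), 593 to 928 and 1221 to 1816 (both MM1.S hairpins), 1845 to 2512 (H929 shRNA2 higher), 768 to 1256 (both H929 hairpins higher), 227 to 353 (both lines higher), 3708 to 4685 (between MM1.S hairpins), 3268 to 4595 (H929 scramble groups), 823 to 2101 (line difference with shRNA2) and 382 to 1008 (with both); fewer libraries lower the power of each test. For the other changes the cause was not tested. Other counts stayed within 1.5 times.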
